A study of Mus musculus with 4 samples.

How the data were processed

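RNA was sequenced from cardiac cushions, the valve-forming swellings of the outflow tract and atrioventricular canal, dissected from mouse embryos at embryonic day 14.5. Per the labels' protocols, tissue was taken by the GFP signal of a Cre reporter, total RNA was depleted of ribosomal RNA, and libraries were made with the ScriptSeq kit. There were 4 libraries, 2 from wildtype embryos and 2 from embryos in which Brg1 (gene symbol Smarca4), the ATPase of the SWI/SNF chromatin remodelling complex, was deleted with Nfatc1-Cre, which acts in the endocardium. The sources used here do not say whether a library held 1 embryo or several, so p-values measure the spread between these libraries, which may be technical in part.

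The authors deposited a table of raw counts per gene symbol. Per the submitters' processing notes, Bowtie2, TopHat2, SAMtools, HTSeq and edgeR were used with the mm10 build; versions, gene annotation and strand setting are not given in the sources used here. The count table held 23337 gene rows. Rows that name no gene stayed out of library sizes and tests: reads outside any feature made up 51.8% to 54.4% of all tallied reads, reads aligned to several places 16.1% to 17.0%, and ambiguous reads 0.187% to 0.210%. Reads in genes numbered 19218820 and 15790338 in wildtype replicates 1 and 2, and 22426537 and 14104458 in mutant replicates 1 and 2. At these depths, 3 reads correspond to 0.134 to 0.213 CPM. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Without a known strand setting, reads of overlapping or antisense genes cannot be told apart.

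The authors also deposited a table of their own edgeR comparison with log2 fold changes, log2 CPM, a likelihood ratio score, unadjusted p-values, adjusted p-values and, for the rows past an adjusted p of 0.05, a fold change ratio. Per the file headers and by comparison with the counts, its log2 fold changes are wildtype over mutant, and they are given here as mutant over wildtype. It held 11507 rows, 3 of which were totals outside genes. Genes with a CPM over 1 in at least 3 libraries, over totals that include such rows, came to the same 11507 rows.

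Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter, which left 14316 genes, and the quasi-likelihood F test for genotype, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. The standard error of a log2 fold change was taken from the fold change and its F statistic. Gene lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, and repeated with an estimated correlation and with fry. Of 33 lists, 31 could be tested; mitochondrially encoded genes had no row in the table and melanocyte markers had 4 tested members. The comparison, its test, the lists, 15 alternative settings for the count of genes and the rule for naming genes were set before the data were examined. A further 10 settings and 5 gene lists were added after seeing the data.

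Named genes were Smarca4 and Nfatc1, then up to 12 per direction past the threshold whose mutant libraries both lay on the same side of both wildtype libraries, then up to 5 next by p. Predicted, clone-named, small RNA and sex-linked genes were left out of that step. From each list came the members past the threshold or, with fewer than 2, the 2 of highest mean CPM. The rule lets lists of other cell types and RNA quality be given by count alone, which was done where camera did not call them. Gene positions and exon lengths are from GENCODE M21 on the mm10 assembly, build 38, matched by symbol or older symbol for 22848 of 23342 row names.

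The series describes the samples as 2 pairs of mutants and littermates, and replicate numbers 1 and 2 recur in both genotypes. Deviations of same-numbered libraries from their group means correlated at 0.144 across genes, which are not independent replicates, and at 0.0448 with a stricter filter. A fit with the replicate number as a block gave log2 fold changes within 0.0405 of the authors' deposited table. Without the block, 493 of 11507 rows differed by more than that, by up to 2.82 for Xist and 0.598 for the next gene; the median difference was 0.0099 with the block and 0.0107 without it. The numbers were therefore read as pairs, as the authors' model did. This was settled after the number of calls under both fits had been seen. The fit without the block stayed the main one, as set beforehand, and blocked values stand beside it where the call changed for a named gene or list.

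Alternatives covered the replicate block, RLE and upper-quartile scaling, no filter, a filter of CPM 5 in 2 libraries, DESeq2 1.42.0, the edgeR likelihood ratio test, limma-voom, the 10 most abundant genes and haemoglobins left out, each library left out, and a threshold of 0.10. The fits were tested on simulated counts for this comparison over 14316 genes, with 50 genes changed at each fold. The fit without a block recovered 8 genes at 1.5-fold, 34 at 2-fold, 49 at 4-fold and 46 at 8-fold, with 3 false calls; the fit with the replicate block recovered 4, 34, 41 and 49, with 5 false calls. With camera, 20 of 20 simulated lists shifted by 0.4 on the log2 scale were recovered and 1 of 20 unshifted lists was called. Simulated genes took their variation from the average trend over expression, without the scatter of single genes around it. Recovery and false calls in the data may therefore be worse than these counts. Simulated genes also varied independently, and lists were scored at an unadjusted p under 0.05. The simulation therefore cannot show how often the preset correlation calls lists of correlated genes.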

Results

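Transcript levels were measured by total RNA sequencing in cardiac cushions of mouse embryos at embryonic day 14.5, in 2 wildtype libraries and 2 libraries from Nfatc1-Cre Brg1 mutants. Between 14104458 and 22426537 reads per library fell in genes. Ttn, which encodes the sarcomere protein titin, took the largest share, 2.99% to 3.66% of gene reads. Log2 CPM correlated across genes at 0.987 between the wildtype libraries, at 0.981 between the mutant libraries, and at 0.981 to 0.984 between libraries of different genotype. The biological coefficient of variation was 14.5%.

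Smarca4, the deleted gene, lies on chromosome 9 at 21616169 to 21704230. It measured 251 and 231 CPM in wildtype replicates 1 and 2, and 282 and 239 CPM in mutant replicates 1 and 2. Its log2 fold change was 0.11 ± 0.14 (SE), with an adjusted p of 0.979 by edgeR's quasi-likelihood test. No fall was thus seen in the mutant libraries, and these counts do not bear out the genotype labels. Counts over the whole gene include transcripts outside the deleted part and cells outside the Cre lineage. The absence of a fall therefore does not decide whether the gene was deleted. Nfatc1, the endocardial transcription factor whose locus drives the Cre, measured 44.3 and 55.2 CPM in wildtype and 52.99 and 34.5 CPM in mutant replicates 1 and 2.

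The comparison asked which transcripts differ in the cushions when Brg1 is deleted in the endocardial lineage. Ptprc, the leukocyte surface phosphatase CD45 (chromosome 1, 138062861 to 138175708), rose 3.91-fold, from 7.11 ± 0.566 to 27.7 ± 2.36 CPM (SD, n = 2 libraries each; log2 fold change 1.97 ± 0.18, edgeR adjusted p = 0.0119). Ccr2, the chemokine receptor of inflammatory monocytes (chromosome 9, 124101950 to 124113557), rose 11.7-fold, from 0.819 ± 0.180 to 9.52 ± 1.28 CPM. Nptx1, a secreted neuronal pentraxin (chromosome 11, 119538719 to 119547753), rose 5.03-fold, from 6.23 ± 1.81 to 31.1 ± 4.69 CPM. Col23a1, a transmembrane collagen (chromosome 11, 51289920 to 51583918), fell from 44.2 ± 0.915 to 17.1 ± 0.203 CPM, a ratio of 0.387.

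The other genes that rose were Hemgn, a nuclear protein of blood progenitors, 12.7-fold (adjusted p = 0.0252), Mpeg1, a macrophage perforin, 3.26-fold (0.0252), Cybb, the phagocyte NADPH oxidase subunit, 3.03-fold (0.0351), Fyb, an adaptor of T cells and myeloid cells, 3.45-fold (0.0390), and Ctss, the protease cathepsin S, 2.51-fold (0.0499). Hemgn was at 0.419 CPM in wildtype, close to the counting limit. In each of these 9 genes both mutant libraries lay on the same side of both wildtype libraries, which chance gives for 33.3% of genes and which 33.2% of tested genes showed. The genes next by p did not pass in the fit without the block. With the replicate block all 9 of them passed, with edgeR adjusted p from 2.126e-04 for Ccl2 to 0.00646 for Npr3. All 9 also passed by DESeq2 and 0 by limma-voom. The authors' deposited table has the 5 lower ones past its threshold and no row for the higher ones. Among those with higher values were Scg3, a granin of neuroendocrine secretory granules, at a log2 fold change of 2.61 ± 0.38, Ccl2, a monocyte chemokine, at 2.17 ± 0.32, Ikzf1, a lymphoid transcription factor, at 2.05 ± 0.30, and Disp2 at 2.60 ± 0.41. Among those with lower values were Npr3, the natriuretic peptide clearance receptor of endocardium, at -0.88 ± 0.12, Nppa, atrial natriuretic peptide, at -1.08 ± 0.16, Smoc1, a matricellular protein, at -1.81 ± 0.25, Enpp2, autotaxin, at -1.84 ± 0.27, and Slc22a23 at -1.17 ± 0.17.

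**Figure D1:**
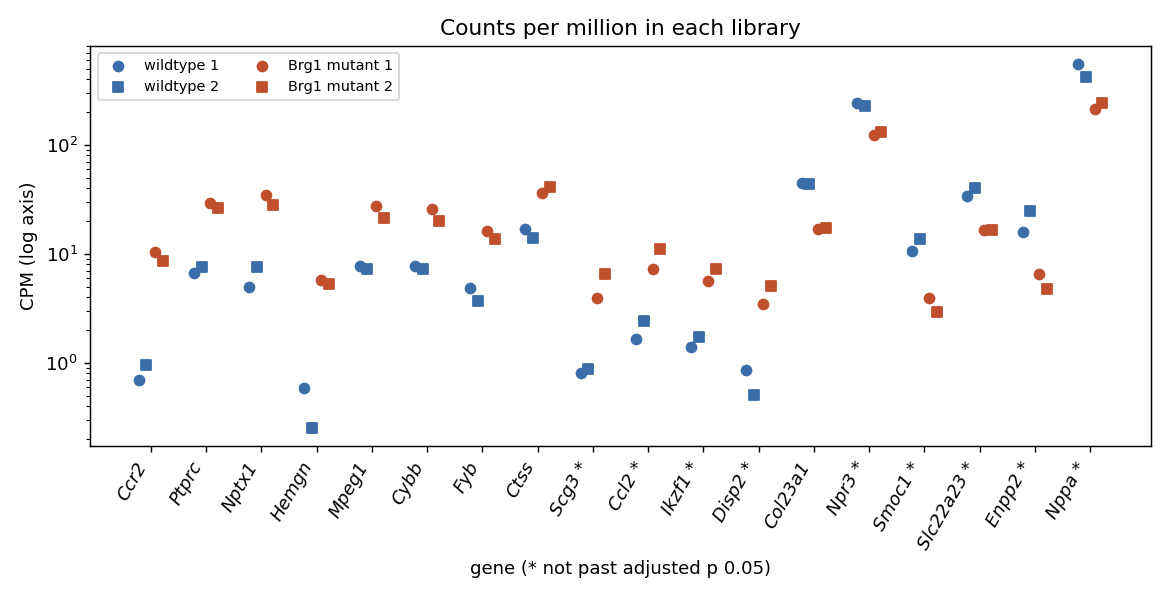
CPM (log axis) of the genes named by p, with 1 point per library: circles are replicate 1, squares replicate 2, blue wildtype and red Brg1 mutant. Ptprc lies at 6.71 and 7.51 CPM in wildtype and at 29.4 and 26.1 CPM in mutant libraries, and starred genes did not pass the test.

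In all, 9 of 14316 genes passed, 8 higher and 1 lower in the mutant; 555 genes were higher and 272 lower at an unadjusted p under 0.05. With the replicate number as a block, 127 genes passed, 99 higher and 28 lower, among them all 9, and 4 of the 127 were Y-linked genes. With the block and the filter of the authors' table, chosen after seeing the data, 16 were higher and 14 lower. The count of calls ranged from 0 to 443 over 25 other settings, 10 of them added after seeing the data; without wildtype replicate 2 it was 3 and without mutant replicate 2 it was 443. The authors' deposited table held 43 rows past an adjusted p of 0.05, 22 higher and 21 lower in the mutant; 7 of the 9 genes were among them, and Ccr2 and Hemgn had no row in it.

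**Figure D2:**
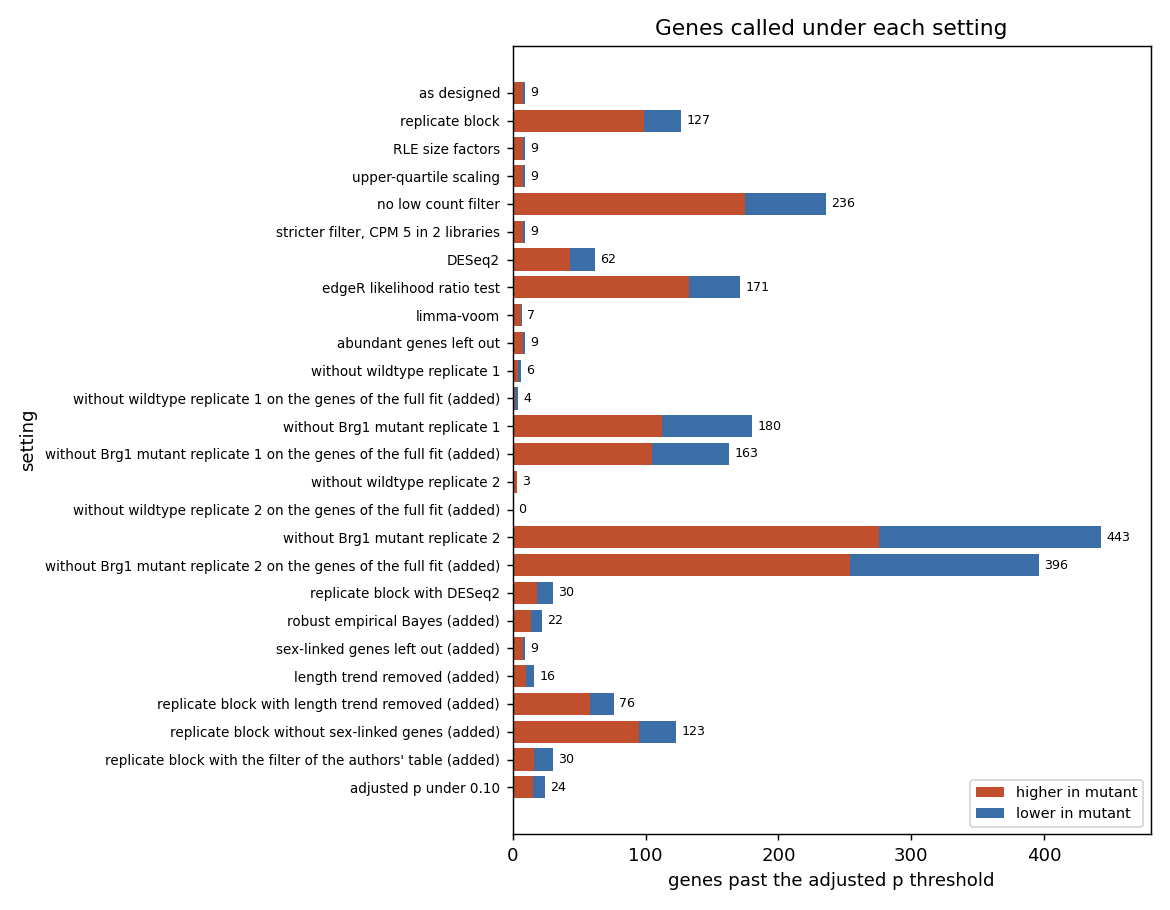
Number of genes past the adjusted p threshold under each setting, on an axis from 0, with genes higher in the mutant in red and lower in blue; settings added after seeing the data are marked. The count is 9 as designed, 127 with the replicate block and 443 without mutant replicate 2.

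The libraries differed in sex-linked transcripts. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d had 0 reads in wildtype replicate 1 and mutant replicate 1, 11 to 28 reads in wildtype replicate 2 and 1131 to 3384 reads in mutant replicate 2. Xist measured 13.3 CPM in mutant replicate 2 and 2047 to 2659 CPM in the other libraries. By these transcripts, mutant replicate 2 was almost wholly male and the other libraries almost wholly female. Pair 2 therefore differs in sex as well as genotype. Leaving out sex-linked genes left the count at 9, but the 9 genes were not on that list. An effect of sex on other genes was not tested.

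Leukocyte genes stood out among the gene lists. The macrophage and leukocyte list rose (camera adjusted p = 9.798e-32), with a median log2 fold change of 0.88 over 17 tested genes. Its adjusted p was 0.328 with an estimated correlation and 0.101 with fry. Of these genes, 15 passed adjusted over the list alone, all higher, and 1, Ptprc, passed over all genes, or 5 with the replicate block. Mrc1 and Lcp1, the members of highest level beside it, had log2 fold changes of 0.22 ± 0.15 and 0.45 ± 0.14. The list's median was 0.85 in pair 1 and 0.89 in pair 2. Of markers of another tissue, the hepatocyte genes Alb and Afp, picked after their values were seen, had log2 fold changes of 2.11 ± 0.51 and 1.40 ± 0.35; edgeR adjusted p was 0.264 and 0.305, and 0.0176 and 0.0275 with the block.

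The interferon and inflammatory list rose, with a median of 0.70 over the 17 of 23 genes that could be tested and 7 higher adjusted over the list alone. Its member Il1b passed the low count filter only through the mutant libraries. The adjusted p was 0.328 with an estimated correlation. Over all genes 0 members passed, or 5 with the replicate block, Ccl2 among them, and DESeq2 called 1. Its 2 members of highest level, Vcam1 and Cxcl12, had log2 fold changes of -0.01 and 0.37. Il1b had 0 wildtype reads and an edgeR adjusted p of 0.134, or 0.00485 with the block, and with it at its bound of at least 4.75-fold the median was also 0.70. The erythroid list rose, with a median of 0.73 over the 10 of 20 genes that could be tested, of which 2 passed adjusted over the list alone. The adjusted p was 0.599 with an estimated correlation. Over all genes 0 members passed, or 2 with the replicate block, and DESeq2 called 1. Embryonic globin Hbb-y, its most abundant tested member, measured 0.28 ± 0.14 and Tfrc, the transferrin receptor, -0.22 ± 0.18. The adult globins Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 had 0 or 1 reads in each library, so they give no measure of red cells here.

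Fibrillar collagen and crosslinking genes rose as a list, with a median of 0.21 over 23 genes (camera adjusted p = 3.669e-05). The adjusted p was 0.767 with an estimated correlation. The list had 0 members past the threshold by edgeR, with 4 higher at an unadjusted p under 0.05 and 0 called by DESeq2 or with the block. Col3a1 and Postn, the members of highest level, had log2 fold changes of 0.10 ± 0.16 and -0.03 ± 0.15. The list's median was 0.37 in pair 1 and 0.0023 in pair 2, and without mutant replicate 1 its median was 0.06 and its adjusted p 0.168; without mutant replicate 2 its median was 0.32. Hypoxia and glycolysis genes rose as a list, with a median of 0.26 over 19 genes; Pkm2 and Aldoa, glycolytic enzymes, measured 0.26 and 0.19. The adjusted p was 0.624 with an estimated correlation, and 0.0507 without mutant replicate 2. Immediate early and stress genes rose as a list, with a median of 0.16 over 22 genes, Klf6 at -0.01 and Jun at 0.25; the adjusted p was 0.767 with an estimated correlation, and the list's call was lost without mutant replicate 1 (median -0.03, adjusted p = 0.520) and without wildtype replicate 2 (0.14, 0.218). Its median was 0.39 without wildtype replicate 1 (4.847e-04) and 0.31 without mutant replicate 2 (0.00161).

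Cardiomyocyte markers fell as a list, with a median of -0.16 over 25 genes, 3 of them lower adjusted over the list alone. The adjusted p was 0.767 with an estimated correlation. Over all genes 0 members passed, or 1, Nppa, with the replicate block, and DESeq2 called 3. Ttn measured -0.24 ± 0.18 and Myh7, a myosin heavy chain, -0.02 ± 0.18. The median was -0.34 in pair 1 and 0.0043 in pair 2; it was -0.065 without mutant replicate 1, -0.076 without wildtype replicate 1, -0.27 without wildtype replicate 2 and -0.28 without mutant replicate 2. Nuclear genes of oxidative phosphorylation fell as a list, with a median of -0.10 over 25 genes, Atp5b at -0.17 and Atp5a1 at -0.10; the adjusted p was 0.825 with an estimated correlation, and 0.0940 with a trend over gene length removed. The median was -0.41 in pair 1 and 0.12 in pair 2; it was -0.013 without mutant replicate 1 (adjusted p = 0.950), -0.028 without wildtype replicate 1 (0.511), -0.28 without wildtype replicate 2 (1.085e-04) and -0.39 without mutant replicate 2 (1.603e-08). Of the 8 lists called with the preset correlation, 0 held with an estimated correlation and 0 passed by fry. The fit left 2 residual degrees of freedom, and neither test was tried on simulated lists. Real shifts may therefore have been missed by them.

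The other lists of valve formation did not pass with all 4 libraries, and 0 of their members passed by edgeR. In the endocardial and endothelial list the median was -0.01 over 28 genes, Tek measured 0.11 and Cdh5 0.01, and with the block 1 member, Npr3, fell. The regulators of epithelial-to-mesenchymal transition and cushion mesenchyme had a median of -0.01 over 27 genes, with Vim at 0.28 and Tbx20 at 0.06. Proteoglycan and hyaluronan matrix genes had a median of 0.01 over 22 genes, with Vcan at -0.20 and Hspg2 at 0.18. Their median was 0.15 in pair 1 and -0.12 in pair 2, -0.10 without mutant replicate 1 and 0.14 without mutant replicate 2. Elastic fibre genes had a median of 0.19 over 17 genes, 0.47 in pair 1 and -0.16 in pair 2, with Fbn1 at 0.20 and Fbn2 at 0.19. Cartilage and bone genes (17 tested) had a median of 0.03, 0.26 in pair 1 and -0.42 in pair 2, and included Sox6 at 0.05 and Col11a1 at 0.03, tendon genes (7) Tnc at 0.16 and Col14a1 at 0.29, and matrix proteases and inhibitors (19) Timp3 at -0.04 and Adamts1 at 0.34. In the valve disease list of 24 genes, Col3a1 stood beside Flna at 0.13, and in the second heart field list of 14, Nrp1 was at -0.01 and Mef2c at 0.05. Several of these lists passed by camera with the preset correlation when 1 library was left out. Without mutant replicate 1 these were the mesenchyme list (median -0.094, adjusted p = 0.0211) and cartilage and bone genes (-0.41, 0.00206). Without mutant replicate 2 they were elastic fibre genes (0.38, 1.878e-08), the valve disease list (0.19, 0.00128) and matrix proteases (0.19, 0.0380). Without wildtype replicate 2 they were elastic fibre genes (0.31, 0.00626) and matrix proteases (0.19, 0.0448). The elastic fibre median was -0.019 without mutant replicate 1. An estimated correlation was not computed with a library left out.

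Signalling lists did not pass with all 4 libraries. The medians were 0.07 for Notch signalling over 17 genes, with Notch2 at 0.12 and Hey2 at -0.09, and 0.16 for TGF-beta and BMP signalling over 26, with Bmpr1a at 0.03 and Tgfbr1 at 0.05. They were 0.09 for Wnt signalling over 25, with Sfrp1 at 0.07 and Dkk3 at -0.40, and 0.10 for VEGF, FGF, EGF and neuregulin signalling over 21, with Vegfa at 0.08 and Erbb4 at -0.04. Without mutant replicate 1 these medians were 0.053 for Notch, -0.0037 for TGF-beta and BMP, -0.052 for Wnt and -0.029 for VEGF, FGF, EGF and neuregulin signalling. Without mutant replicate 2 the TGF-beta and BMP list passed (median 0.17, adjusted p = 0.0276). The venous and lymphatic list of 9 genes had Nrp2 at 0.63 and Prox1 at -0.15. Nrp2 was at 0.71 in pair 1 and 0.54 in pair 2 and passed adjusted over the list alone. Over all genes its adjusted p was 0.171 by edgeR and 0.0225 by DESeq2. SWI/SNF subunits (25 tested) had a median of -0.01, with Pbrm1 at -0.01. Mitotic genes (32) had Mki67 at 0.27 and Top2a at 0.02, p53 targets (17) Ccng1 at -0.10 and Plk2 at 0.18, and imprinted growth genes (14) H19 at -0.42 and Igf2r at 0.08. Smooth muscle (11 tested), epicardial (11), neural crest, glial and neuronal (10), epithelial (5) and melanocyte markers (4) had 0 members past the threshold by edgeR. Without mutant replicate 1 the mitotic (adjusted p = 0.0122), epicardial (0.0120), epithelial (0.0165), melanocyte (0.0129) and sex-linked lists passed by camera with the preset correlation. Over the 30 lists without a called member, 521 genes in all, 44 were higher and 16 lower at an unadjusted p under 0.05; DESeq2 called 7, limma-voom 1 and the fit with the block 13. Among the 44 and among the 13, 4 were Y-linked genes, whose reads came almost wholly from mutant replicate 2.

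**Figure D3:**
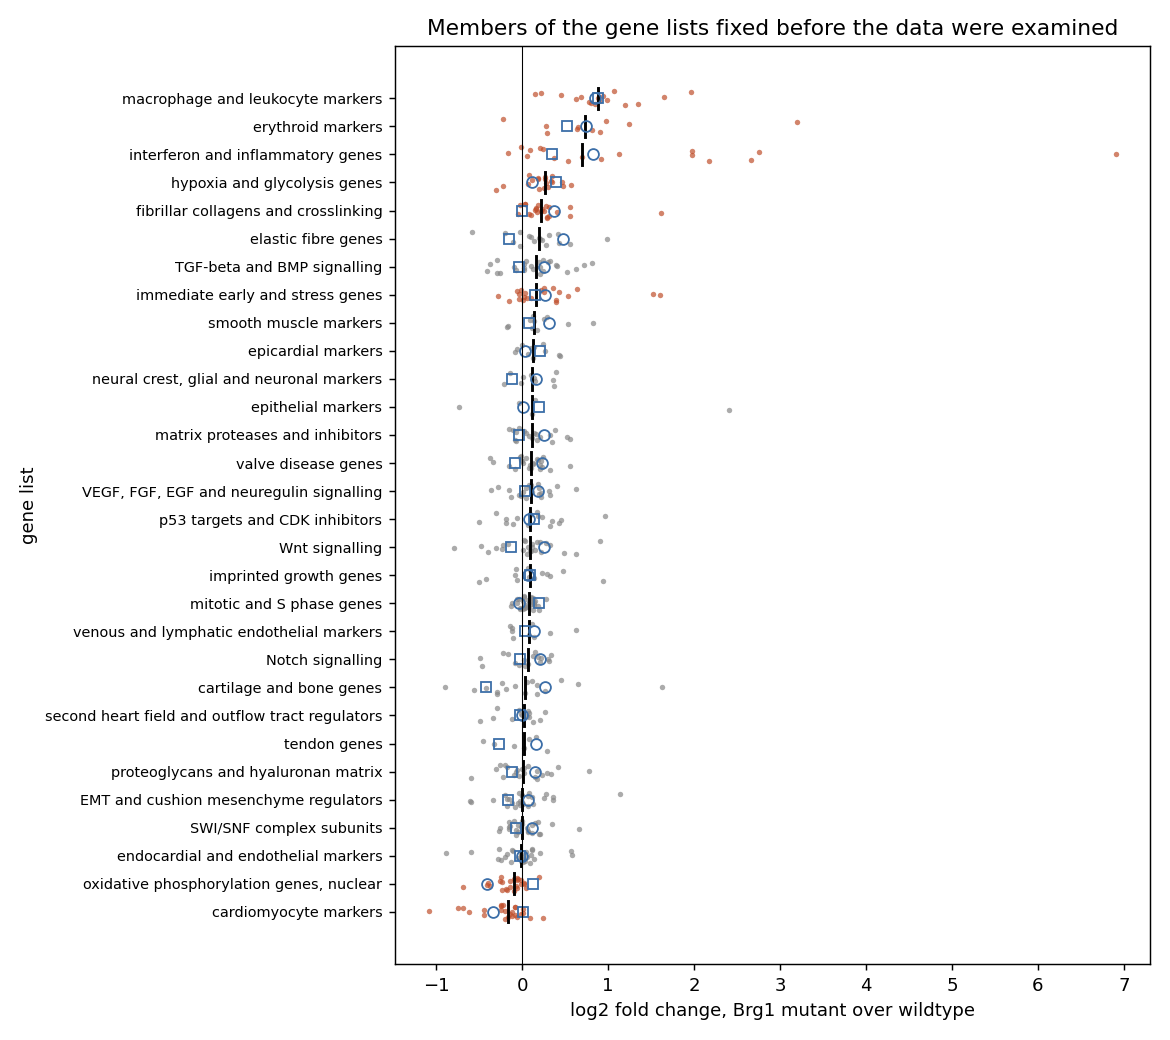
Log2 fold change (mutant over wildtype) of each tested member of 30 lists, with 1 point per gene; black bars are list medians, open circles and squares the medians of pair 1 and pair 2, and red points mark lists called by camera with the preset correlation. The leukocyte list has medians of 0.85 and 0.89 in the pairs, and the fibrillar collagen list 0.37 and 0.0023.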

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

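The robust prior, the removal of sex-linked genes or of the length trend, the authors' filter, the libraries left out on the genes of the full fit and the alternatives for the replicate correlation were tests chosen after the results were seen. The count of 9 genes became 236 without a low count filter, 62 with DESeq2, 171 with the edgeR likelihood ratio test, 24 at a threshold of 0.10, 22 with a robust prior and 16 with the length trend removed. With the replicate block it became 127, or 30 with DESeq2, 76 with the length trend removed, 123 without sex-linked genes and 30 with the authors' filter; the block changed the prior degrees of freedom from 7.14 to 21.9. Leaving out 1 library gave 3 (wildtype 2) to 443 (mutant 2) calls, with 6 without wildtype 1 and 180 without mutant 1; on the genes of the full fit these were 0, 396, 4 and 163. A lone library is assumed there to vary like the other group. All 9 genes passed in 19 of 25 settings; limma-voom kept 6. Without wildtype 1, 4 of the 9 passed, and without wildtype 2, 2; on the genes of the full fit 2 and 0. The cause was not tested. The 8 lists became 0 with an estimated correlation and 0 with fry, and 9 with the paired fit, which added the sex-linked list and with an estimated correlation gave 0. Residual degrees of freedom were 2 without the block and 1 with it, so these tests had little power. Leaving out 1 library gave 7 lists (wildtype 1), 9 (wildtype 2), 12 (mutant 1) and 11 (mutant 2), with 7, 7, 5 and 7 of the 8 among them, and removing the length trend gave 7 with or without the block. No filter gave 9 lists and the stricter filter 8, 7 of them shared. Smarca4 was at 0.11 with the replicate block. The correlation of same-numbered libraries was 0.0448 under the stricter filter.

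Directions of the 9 genes held in all 162 fits, which reuse the same libraries. Both mutant libraries lay on the same side of both wildtype ones in each gene. Leaving out 1 library could therefore hardly turn a direction, and this is no separate check. Of other named genes, each short of the threshold as designed, upper-quartile scaling turned Pbrm1 (0.0043), Nrp1 (0.0075), Myh7 (0.0017), Vcam1 (0.0050) and Klf6 (0.0045), and the replicate block with the length trend removed turned Top2a (-0.0045). With 1 library left out, log2 fold changes crossed 0 over these ranges: Smarca4 -0.015 to 0.23, Nfatc1 -0.53 to 0.099, Pbrm1 -0.062 to 0.036, Cdh5 -0.041 to 0.067, Tbx20 -0.012 to 0.14, Hspg2 -0.011 to 0.35, Col3a1 -0.021 to 0.23, Postn -0.13 to 0.078, Fbn2 -0.019 to 0.38, Sox6 -0.16 to 0.24, Col11a1 -0.017 to 0.074, Tnc -0.16 to 0.42, Timp3 -0.13 to 0.058, Notch2 -0.040 to 0.28, Hey2 -0.36 to 0.14, Bmpr1a -0.060 to 0.11, Tgfbr1 -0.027 to 0.13, Sfrp1 -0.12 to 0.29, Vegfa -0.037 to 0.19, Erbb4 -0.13 to 0.037, Flna -0.0023 to 0.25, Nrp1 -0.030 to 0.011, Mef2c -0.033 to 0.15, Myh7 -0.19 to 0.18, Tfrc -0.49 to 0.11, Top2a -0.14 to 0.17, Ccng1 -0.29 to 0.11, Plk2 -0.052 to 0.46, Vcam1 -0.14 to 0.11, Klf6 -0.12 to 0.10, Jun -0.033 to 0.49, Atp5a1 -0.21 to 0.035 and Igf2r -0.021 to 0.17. The immediate early list's median ran from -0.032 to 0.39. The causes were not tested.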

Other observations

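The 5 lists added after seeing the data, and all tests below except that of liver tissue, were chosen only after the result was seen. Monocyte and granulocyte genes with enough reads to test (4 of 17) included Plac8 at a log2 fold change of 3.34 beside Ccr2. The granule enzyme Mpo had 2 and 0 reads in wildtype and 21 and 10 reads in mutant replicates 1 and 2. Antigen presentation genes had a median of 1.24 over the 8 of 12 genes with enough reads to test. Cd74, the invariant chain, had 9 and 1 reads in wildtype and 60 and 37 in mutant replicates 1 and 2. It thus passed the low count filter only through the mutant libraries. Medians of lists with many untested members may therefore reflect the filter in part. Resident tissue macrophage genes had a median of 0.32 over 17, with Csf1r at 0.99 and Stab1 at -0.06; that median was 0.63 without mutant replicate 1 and 0.15 without mutant replicate 2. With an estimated correlation, camera gave an adjusted p of 0.0626 for antigen presentation genes and 0.136 for resident macrophage genes. Here and below, lists added later were adjusted among themselves, so these values cannot be set beside those over 31 lists. Unadjusted, that p was 0.0156 for antigen presentation genes and 0.0113 for the macrophage and leukocyte list. The genes named here were picked after their values were seen, and of them Ccr2 passed the test over all genes. Plac8, Cd74, Csf1r and Mpo had edgeR adjusted p of 0.198, 0.143, 0.110 and 0.224, and 0.00114, 0.00215, 0.00980 and 0.0294 with the replicate block; in the authors' table Csf1r was at 4.401e-04.

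Leukocyte genes were higher in both mutant libraries. A smaller share of the main cushion cell type would raise markers of the other cell types alike. The leukocyte median exceeded that of smooth muscle, epicardial, neural and epithelial markers by 0.75 ± 0.08 (SE). The erythroid list, with a median of 0.73, was not part of that comparison. The difference therefore speaks only to the lists compared. Standard errors of list medians, here and below, are over genes of the same libraries. They do not measure the spread between libraries or embryos. Liver carried over in the dissection stays open: Alb and Afp had log2 fold changes of 2.11 and 1.40 and the list of 8 hepatocyte genes a median of 0.45 (camera adjusted p 5.788e-04, or 0.184 with an estimated correlation), but that median was 0.044 in pair 1, 0.64 in pair 2 and -0.11 without mutant replicate 2, and the 6 genes without that pair had 0.17 ± 0.28. Blood carried over stays open too: the erythroid minus leukocyte median was -0.10 ± 0.22 in pair 1 and -0.36 ± 0.48 in pair 2, within the error, whereas 5 erythroid genes over 10 CPM, a limit set after their values were seen, had a median of 0.29, which differed from the leukocyte median by -0.59 ± 0.27. An effect of the genotype on the number or state of leukocytes may add to the pattern and was not tested.

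Neuronal genes such as Nptx1 and Scg3 were among those with higher values in both mutant libraries. Nerve tissue carried over would raise neuronal genes. The neural crest, glial and neuronal list had a median of 0.12 ± 0.09 over the 10 of 19 genes that could be tested. Its median was 0.16 in pair 1 and -0.12 in pair 2, and -0.081 to 0.21 with 1 library left out. The list also holds crest and glial genes, so its median cannot exclude nerve tissue. A candidate explanation is release of targets of REST, the repressor of neuronal genes. Without 4 that prompted the idea and those shared with the neural list, 27 targets had a median of 0.30 ± 0.12. That median was at percentile 99.5 of 10000 random lists matched on expression. Random lists take no account of correlation between genes. Some lists that camera did not call lay as high, with elastic fibre genes at 99.99 and the valve disease list at 99.68. The percentile therefore does not set REST targets apart. Nerve tissue could raise REST targets too, since they are neuronal genes. The full list of 33 had a median of 0.42 in pair 1 and 0.06 in pair 2, 0.15 without mutant replicate 1 and 0.22 without wildtype replicate 1, and an adjusted p of 0.09998 with an estimated correlation. The idea came from 4 genes of the same libraries that passed with the replicate block, so this is a hypothesis only.

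Fibrillar collagen genes were higher as a list. A trend over gene length differed between pairs, with correlations across genes of 0.26 in pair 1 and -0.17 in pair 2, but with it removed the median was 0.19 and the camera adjusted p 6.452e-04. With an estimated correlation, and the trend left in, the adjusted p was 0.767. Mutant replicate 1 alone may account for the shift, since without it the median was 0.0591. Whether that library differs by genotype or by dissection was not tested.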
